A study of Mus musculus with 6 samples.

How the data were processed

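Gene expression was measured on 6 Illumina mouse bead arrays, each loaded with RNA from hematopoietic stem cells sorted from wild-type mice. Per the labels, 3 samples came from mice given phosphate-buffered saline (PBS) and 3 from mice given interferon alpha (IFNa), and the series' design text describes them as 3 biological replicates per group. Per the labels' protocols, RNA was isolated with an Arturus kit, 2.5 ng was amplified with an isothermal NuGEN system, and the product was labelled with biotin. The type of array follows from the probe names.

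The deposited value table holds linear intensity for 46089 probes on each of the 6 arrays. How the authors scanned the arrays, treated the background and normalized the values is not given in the sources used here. From the values, the arrays had been brought to a common scale, with medians from 187 to 189, and no background had been subtracted, since the lowest intensity on any array was 115. An intensity that still contains background understates the fold change of dim genes. The second deposited table holds 6 signal columns and 6 detection columns whose names match no single sample, so these 12 columns of per-sample values were not used.

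The analysis fixed before the data were examined called for background correction and quantile normalization with limma's neqc and for a filter on detection p-values. Both needed the unused columns. The test was therefore run on log2 of the authors' intensity without further normalization, which had been planned as an alternative, and the filter was replaced by a background estimate from the values. On each array the mode of the log2 values was taken as the centre of the background (density bandwidth 0.05), the values below the mode were mirrored above it, and the threshold was set where 1% of this mirrored background would lie higher. The share of the tail was set at 0.01. Thresholds ran from 202 to 215 intensity units. Above them lay 18757, 18577 and 19168 probes on PBS replicates 1 to 3 and 16426, 17427 and 18610 on IFNa replicates 1 to 3, or 35.6% to 41.6% of the probes. A probe was tested where it exceeded the threshold on at least 3 of the 6 arrays. This kept 18646 probes and removed 27443. The number of arrays limits the precision, and the median standard error of a gene's log2 difference was 0.20.

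Probes were named from the platform annotation, with symbols updated through the mouse gene table of GRCm38.p6, which served only for names and for the order of genes along chromosomes. Of the 46089 probes, 35667 had 1 gene symbol, 0 had several and 10422 had none. Names came through the Entrez identifier for 28519 probes and through a symbol or synonym for 7076, and 72 kept the platform's name. A gene was represented by its tested probe with the highest mean over all 6 arrays, which gave 9860 genes beside 2822 unnamed probes. Counts of genes refer to that probe, and in the text other probes of a named gene are given only for the larger disagreements.

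Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 6 arrays, group as the only term, two-sided). P-values were adjusted by Benjamini-Hochberg over all 18646 tested probes, with a threshold of 0.05. Differences are IFNa minus PBS on the log2 scale with the moderated standard error. Where no array of a group exceeded background, the fold is a bound: the mean of the brighter group was set against the mean, over the dimmer group's arrays, of the higher of the background threshold and the probe's own value, and it is written as "at least". Before the data were examined, 20 gene lists and 8 lists of cell type markers were fixed, with 550 entries, of which 515 were on the array. The 20 lists covered core interferon-stimulated genes, interferon receptor, JAK-STAT and IRF genes, interferon-inducible GTPases, nucleic acid sensing, MHC class I and class II presentation, sorting markers, stem cell identity, mitosis and G2/M, G1/S and DNA replication, CDK inhibitors, D cyclins and growth drivers, p53 targets, cell death, ribosome biogenesis, glycolysis, oxidative phosphorylation, immediate early genes, NF-kB and inflammatory mediators, and adhesion. The 8 marker lists covered megakaryocytes, erythroid cells, granulocytes and myeloid progenitors, monocytes with macrophages and dendritic cells, B cells, T and NK cells, early lymphoid progenitors, and endothelial and stromal cells. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation between genes of 0.01. P-values were adjusted by Benjamini-Hochberg over 27 lists. With this preset the p-value takes the genes as units and does not measure the spread between the 3 arrays of a group. Camera with an estimated correlation and fry, which tests whether a list's own genes move one way, were alternatives. A call lost with an estimated correlation does not by itself show correlated genes. The estimate for CDK inhibitors, -0.0063, lay below the preset 0.01, and their camera p still went from 0.0132 to 0.0586. Members past the threshold were also counted with p-values adjusted over the list alone.

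The genes named in the text follow a rule fixed before the data were examined. They are the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, up to 4 called members of each list by size of the difference or, for a list with none, the tested member with the smallest p, and 17 genes fixed by name, of which those tested are given whatever their result. Genes outside this rule are said to have been chosen after their values were seen.

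The code was tested on simulated arrays of the same 18646 probes. With 50 probes changed at each size, 0% of 1.41-fold, 14% of 2-fold, 76% of 4-fold and 94% of 8-fold changes were recovered, with 5 unchanged probes called. No probe was called in a simulation with nothing changed. Of 20 lists shifted by 0.5 on the log2 scale 20 were called, with 0 unshifted lists. The simulated probes were drawn independently, while the MHC class II list had an estimated correlation of 0.331. The simulation therefore does not test the list calls for correlated genes. Alternatives covered the filter on dim probes, the variance model, array weights, the replicate number as a block, the mean of a gene's probes, stricter thresholds, the list test and leaving out each array in turn. Background correction by normexp with an offset of 16 or 50, quantile normalization, cyclic loess, median centring, and filters on all 6 arrays or on a 5% tail were chosen after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.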

Results

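Expression was profiled in hematopoietic stem cells, the cells that maintain all blood lineages, from 12-week-old female C57/BL6 mice that received PBS or IFNa 16 h before the cells were isolated. IFNa is a type I interferon, an antiviral cytokine. Its dose is printed in the labels without a superscript and is read here as 5000000 U per kg. The cells were sorted as the CD150-positive, CD48-negative part of a gate the labels call LK. The labels name them hematopoietic stem cells and do not say whether they were also selected for Sca-1, which separates stem cells from other progenitors. The source name also speaks of 4 weeks after a transplant, which the treatment protocol does not mention. Each group held 3 arrays, and every value below rests on n = 3 per group. Median intensity was 187 to 189 on all 6 arrays, and 35.6% to 41.6% of the 46089 probes exceeded background. Over the tested probes, arrays correlated at 0.940 to 0.949 within PBS, at 0.922 to 0.953 within IFNa and at 0.897 to 0.937 between the groups (Pearson's r across probes, which are not independent replicates). The lowest 2 values within IFNa both involved IFNa replicate 1, at 0.922 and 0.927.

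The comparison of IFNa with PBS asks how stem cells of these wild-type mice respond to the cytokine at 16 h. Genes of the antiviral interferon response rose most. Oas2, an oligoadenylate synthetase that senses double-stranded RNA, was 14.4-fold higher (log2 difference 3.85 ± 0.22 SE), from a mean of 7.85 ± 0.10 (SD) in PBS to 11.70 ± 0.41 in IFNa. Isg15, a ubiquitin-like modifier, was 14.0-fold higher (3.81 ± 0.28), and Usp18, the protease that removes it from proteins, was 13.6-fold higher (3.76 ± 0.25). Of 9860 genes tested, limma called 62 higher and 26 lower at an adjusted p under 0.05, and 56 and 22 of these changed at least 2-fold. The 3 arrays of a group all lay on the same side of the 3 others for all 88 called genes. Among all tested genes this held for 2284, or 23.16%, where chance gives 10%. By probe, 107 were higher and 31 lower, among them 20 and 4 unnamed probes. Of the called genes, 41 had other tested probes, and for 11 of these at least 1 such probe differed in sign, with 0 called in the opposite direction. A further 10 genes had a called probe other than the brightest and are not in these counts, all of them higher: Ddx24, Etnk1, Ifi213, Lgals9, Ly6e, Mlkl, Parp14, Phf11d, Psmb10 and Sp100. These 10 were named after their values were seen. The median difference of all tested genes was -0.0085. The counts fell whichever array was left out: they were 17 higher and 1 lower without PBS replicate 1, 18 and 1 without PBS replicate 2, 22 and 1 without PBS replicate 3, 25 and 4 without IFNa replicate 1, 14 and 1 without IFNa replicate 2, and 14 and 3 without IFNa replicate 3. Each such fit had fewer samples, so these falls do not show that the calls rest on any 1 array. All 88 genes kept the sign of their difference in these 6 fits.

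**Figure D1:**
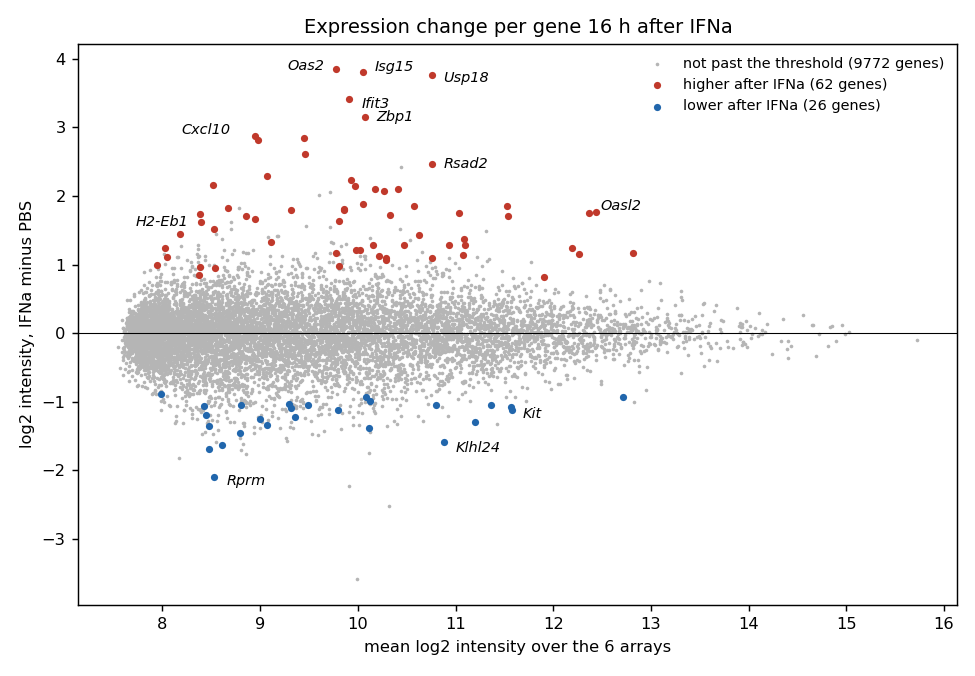
Log2 difference between IFNa and PBS (vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis), with 1 point per gene for 9860 genes. Red points are the 62 genes higher and blue points the 26 genes lower after IFNa at an adjusted p under 0.05, with the highest, Oas2, at 3.85.

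Other large rises included members of the core interferon and nucleic acid sensing lists. Ifit3, which acts in complexes with other Ifit proteins, rose by 3.42 ± 0.31, and Zbp1, a sensor of Z-form nucleic acid, by 3.16 ± 0.26. Rsad2 (viperin), which makes a chain-terminating nucleotide, rose by 2.47 ± 0.17, and Dhx58, an RNA helicase of the RIG-I family, by 2.61 ± 0.18. Apol9b of the apolipoprotein L family rose by 2.82 ± 0.17, Gm4951 by 2.85 ± 0.26, Gm12250 by 2.29 ± 0.18, and Xaf1, a pro-apoptotic partner of Xiap, by 2.24 ± 0.22. Cxcl10, a chemokine for T cells, exceeded background on no PBS array and on all 3 IFNa arrays, and was at least 6.57-fold higher (limma adjusted p = 0.0415). A second, dimmer probe read 2.50 ± 0.54 for Usp18, 1.14 ± 0.24 for Ifit3, 0.64 ± 0.17 for Gm4951 and 0.73 ± 0.18 for Cxcl10. None of these 4 probes passed. Those of Ifit3, Gm4951 and Cxcl10 lay near background, at mean log2 intensities of 8.02, 7.92 and 7.77 over the 6 arrays. Their differences may therefore be understated. Of these 12 genes, Oas2, Isg15, Usp18, Zbp1, Apol9b, Dhx58, Rsad2 and Gm12250 passed the threshold whichever array was left out. Ifit3 missed it in 4 of the 6 fits, Gm4951 in 3, and Cxcl10 and Xaf1 in 5, with adjusted p up to 0.0558, 0.0594, 0.152 and 0.0735.

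Of the 26 genes that fell, 24 were in no fixed list. Rprm, a mediator of cell cycle arrest downstream of p53, exceeded background on all 3 PBS arrays and on no IFNa array, and was at least 3.63-fold lower. Klhl24, a substrate adaptor of a cullin ubiquitin ligase, fell by 1.59 ± 0.17 on the log2 scale, and its other 2 tested probes read -0.94 ± 0.23 and -0.71 ± 0.28. Wtip, a LIM domain protein, fell by 1.69 ± 0.20, and Itga9, an integrin alpha subunit, by 1.63 ± 0.25. The heat shock protein genes Hspa12b and Hspa2 fell by 1.45 ± 0.17 and 1.29 ± 0.18, although a second, dimmer Hspa2 probe read 0.03 ± 0.28. Maged1 fell by 1.39 ± 0.19, Gsta4, a glutathione transferase, by 1.35 ± 0.19, and Gm10419 by 1.34 ± 0.16. Trp53inp1, a p53 target, fell by 1.25 ± 0.18, and Ebpl by 1.23 ± 0.17, with a second probe at -0.67 ± 0.27 and -0.76 ± 0.19. Mpv17, a protein of the inner mitochondrial membrane, fell by 1.19 ± 0.17 by its brightest probe, while its other 3 probes read 0.08 ± 0.13, -0.36 ± 0.14 and -0.50 ± 0.21. None of these 12 genes passed the threshold in all 6 fits with an array left out, where their adjusted p reached 0.078 to 0.168. After normexp background correction with an offset of 16, 10 of the 26 lower genes stayed called and all 26 kept their sign. For the 16 whose call ended (limma adjusted p = 0.0681 to 0.111), the median difference went from -1.09 to -1.30. Their median SE went from 0.16 to 0.22. For the 10 that stayed called, the median difference went from -1.34 to -1.83 and the median SE from 0.17 to 0.24. In both sets the spread widened by relatively more than the fall, so this does not set the lost calls apart.

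**Figure D2:**
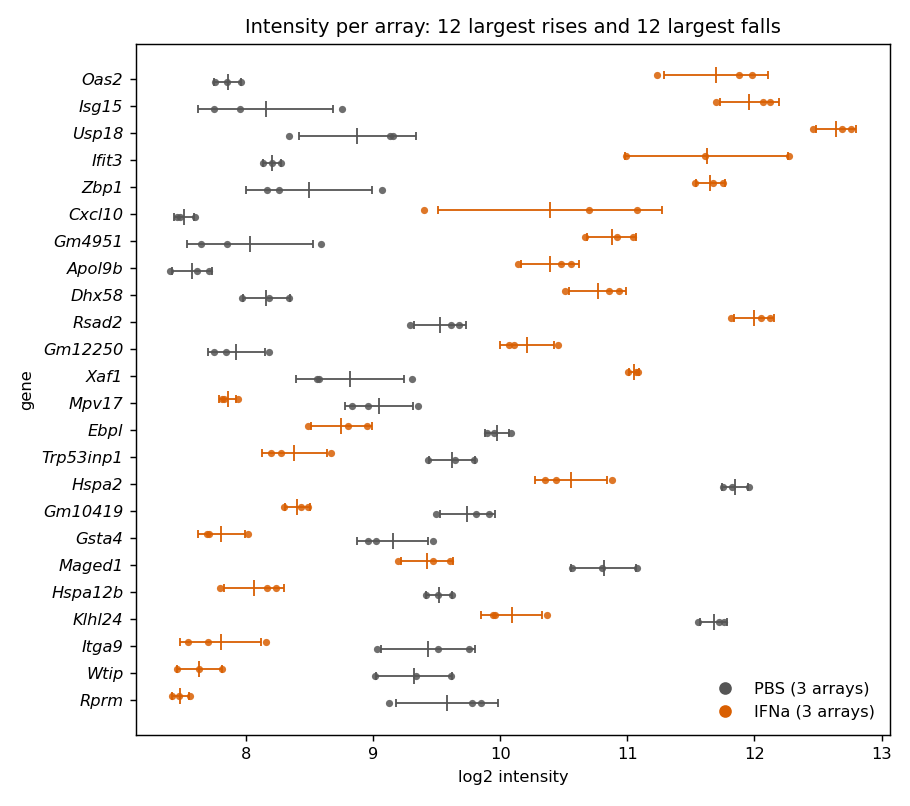
Log2 intensity (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), with 1 point per array, grey for the 3 PBS and orange for the 3 IFNa arrays, and each group's mean with its SD as a bar. The 3 points of either group do not overlap those of the other for any of the 24 genes; Oas2 lay at a mean of 7.85 in PBS and 11.70 in IFNa.

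Core interferon-stimulated genes rose as a list. Of 36 tested, 19 rose over all probes and 34 when p-values were adjusted over the list alone, none fell, and all 36 had positive differences, with a median of 1.59. Parp14, Phf11d and Sp100 of this list are not among the 19 but passed by another probe, at 1.83 ± 0.16, 2.29 ± 0.16 and, with 2 probes, 1.16 ± 0.12 and 1.53 ± 0.16. The list's mean was 9.16 to 9.23 on the PBS arrays and 10.82 to 10.91 on the IFNa arrays (limma camera, adjusted p = 1.23e-39). Interferon-inducible GTPases, which act on the vacuoles of intracellular pathogens, had 12 tested members with a median of 1.21, of which 7 rose over all probes and 12 when adjusted over the list alone (adjusted p = 7.45e-17). Gbp3 and Igtp rose by 2.11 ± 0.22 and 2.11 ± 0.16, Gvin1 by 1.75 ± 0.15 and Gbp7 by 1.71 ± 0.19. Of 17 tested genes of nucleic acid sensing and restriction, 6 rose over all probes and 8 when adjusted over the list alone, with a median of 0.53 (adjusted p = 1.31e-09). Beside Zbp1 and Dhx58 these included Ddx58, which encodes the sensor RIG-I, at 1.64 ± 0.18, and Znfx1 at 1.29 ± 0.19. A dimmer Ddx58 probe, near background at a mean log2 intensity of 7.90 over the 6 arrays, read -0.70 ± 0.25. With an array left out, Igtp passed in all 6 fits, Gvin1 in 4, Gbp3 in 2, Ddx58 in 1 and Gbp7 and Znfx1 in 0, with adjusted p of up to 0.143. All 3 lists passed with an estimated correlation too (adjusted p = 0.00262, 0.0287 and 0.0212). Some paralogs in the Oas and Gbp families are close in sequence, so a probe of one may also bind another's transcript.

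Transcription factors that carry the interferon signal were mixed. Of 16 tested genes of the interferon receptor, JAK-STAT and IRF list, 2 rose over all probes and 3 when adjusted over the list alone, and the list did not pass (median 0.02, adjusted p = 0.109). With an array left out its median ran from -0.02 to 0.11 and its adjusted p from 0.0437, without IFNa replicate 1, to 0.206. Stat2 rose by 1.80 ± 0.16. Irf7, which amplifies type I interferon production, exceeded background on no PBS array and was at least 2.34-fold higher (limma adjusted p = 0.0108). Irf9, the DNA-binding partner of Stat2, differed by 0.66 ± 0.27 (limma adjusted p = 0.318) and the receptor subunit Ifnar2 by 0.30 ± 0.20 (limma adjusted p = 0.54), with overlapping groups for both. Stat2 passed in 4 and Irf7 in 1 of the 6 fits with an array left out, with adjusted p of up to 0.0534 and 0.0732.

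MHC class I presentation genes were higher as a list, while the call for class II depended on the setting. The MHC class I and immunoproteasome list had 20 tested members, with 0 past the threshold over all probes in limma by their brightest probe and 12 higher when adjusted over the list alone. Another probe of Psmb10, an immunoproteasome subunit, did pass, at 1.26 ± 0.15 (limma adjusted p = 0.0198). At an unadjusted p under 0.05, 792 genes were higher and 921 lower over all genes tested. Differences were positive for 19 of the 20, the median was 0.60, and the list's mean was 10.14 to 10.24 in PBS and 10.74 to 10.79 in IFNa (camera adjusted p = 9.3e-10, and adjusted p = 0.0212 with an estimated correlation). H2-T22 differed by 1.10 ± 0.17 (limma adjusted p = 0.0503), and class I genes are close paralogs whose probes may share transcripts. In the MHC class II list, H2-Eb1 rose by 1.52 ± 0.20 but passed in 0 of the 6 fits with an array left out (adjusted p up to 0.132). Of 9 tested members 1 rose over all probes and 4 when adjusted over the list alone. The median was 0.58, or 0.42 with the member below background in PBS at its bound, and the camera adjusted p was 0.0246. That call was lost with an estimated correlation (adjusted p = 0.471), without PBS replicate 1 (median 0.25, adjusted p = 0.148), without IFNa replicate 3 (median 0.16, adjusted p = 0.121) and with probes above background on all 6 arrays (adjusted p = 0.0515), and the list's mean on PBS replicate 3, 8.72, exceeded that on IFNa replicate 1, 8.65.

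Genes that mark stem cell identity were lower as a list. Differences were negative for 24 of 27 tested members, with a median of -0.51, or -0.49 with Fgd5 at its bound, and the list's mean was 9.96 to 10.10 in PBS and 9.51 to 9.65 in IFNa. Camera gave an adjusted p of 1.26e-05, and adjusted p = 0.0423 with an estimated correlation, and the list passed camera whichever array was left out. In limma 0 members passed over all probes, while 8 were lower and 1 was higher when adjusted over the list alone. Ndn, the member with the smallest p, differed by -0.94 ± 0.16 (limma adjusted p = 0.0598). The other 8 were chosen after their values were seen: they were Mecom, a transcription factor needed for stem cell maintenance, at -1.48 ± 0.31 (other probes -1.43 ± 0.25 and -0.58 ± 0.17), the angiopoietin receptor Tek at -0.98 ± 0.29 and its ligand Angpt1 at -0.86 ± 0.24 (other probe -0.19 ± 0.13), Gata2 at -0.60 ± 0.17, Fhl1 at -0.55 ± 0.14 and Zfx at -0.67 ± 0.18 (other probe 0.14 ± 0.22). Fgd5 exceeded background on no IFNa array and was at least 1.40-fold lower (limma adjusted p = 0.0618 over all probes), and Bmi1, a polycomb protein, differed by 0.54 ± 0.15 in the other direction. On the same arrays erythroid markers were higher and megakaryocyte markers lower, with medians of 0.16 and -0.26 (camera adjusted p = 0.049 and 0.033). Both calls were lost with an estimated correlation (adjusted p = 0.372 and 0.471).

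Among the lists of the cell cycle, 1 passed, that of CDK inhibitors and quiescence regulators. Of 13 tested members, 0 passed over all probes in limma and 2, Btg1 at -0.84 ± 0.15 and the inhibitor Cdkn1c at -1.77 ± 0.39, were lower when adjusted over the list alone. That list's median was -0.21 and its camera adjusted p 0.0396. The call was lost with an estimated correlation (camera adjusted p = 0.243) and without PBS replicate 1, PBS replicate 2 or IFNa replicate 3. Without these arrays the medians were -0.19, -0.11 and -0.17 (camera adjusted p = 0.0753, 0.0811 and 0.0771). The call was also lost with probes above background on all 6 arrays (0.0758) and with the 5% background tail (0.064). A variance trend (0.0522) and the replicate number as a block (0.0519) ended it too. Cdkn1a and Cdkn1b differed by 0.05 ± 0.39 and -0.27 ± 0.18. The mitosis and G2/M list had a median of 0.13 over 24 members and an adjusted p of 0.142, with 0 members past the threshold over all probes and 1 higher when adjusted over the list alone, Tpx2, a spindle assembly factor, at 0.94 ± 0.15. Mki67, the proliferation marker, differed by 0.04 ± 0.14. The G1/S and DNA replication list had a median of 0.05 over 22 members (adjusted p = 0.505), with 0 members past either adjustment and the smallest p for Ccne2 at -0.62 ± 0.23. D cyclins, Myc and growth drivers had a median of -0.02 over 14 members (adjusted p = 0.868) and 0 members past either adjustment, with Cdk6 at -0.59 ± 0.24 and Myc at -0.11 ± 0.34. Ribosome biogenesis genes, by contrast, had positive differences for 18 of 20 members, with a median of 0.28 (camera adjusted p = 3.24e-04, but adjusted p = 0.243 with an estimated correlation). The list passed camera whichever array was left out (adjusted p up to 0.0057) and passed fry (adjusted p = 0.0324). No member passed over all probes and 1 was higher when adjusted over the list alone, Bop1, at 1.62 ± 0.27 by its brighter probe and 0.42 ± 0.26 by its other probe.

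**Figure D3:**
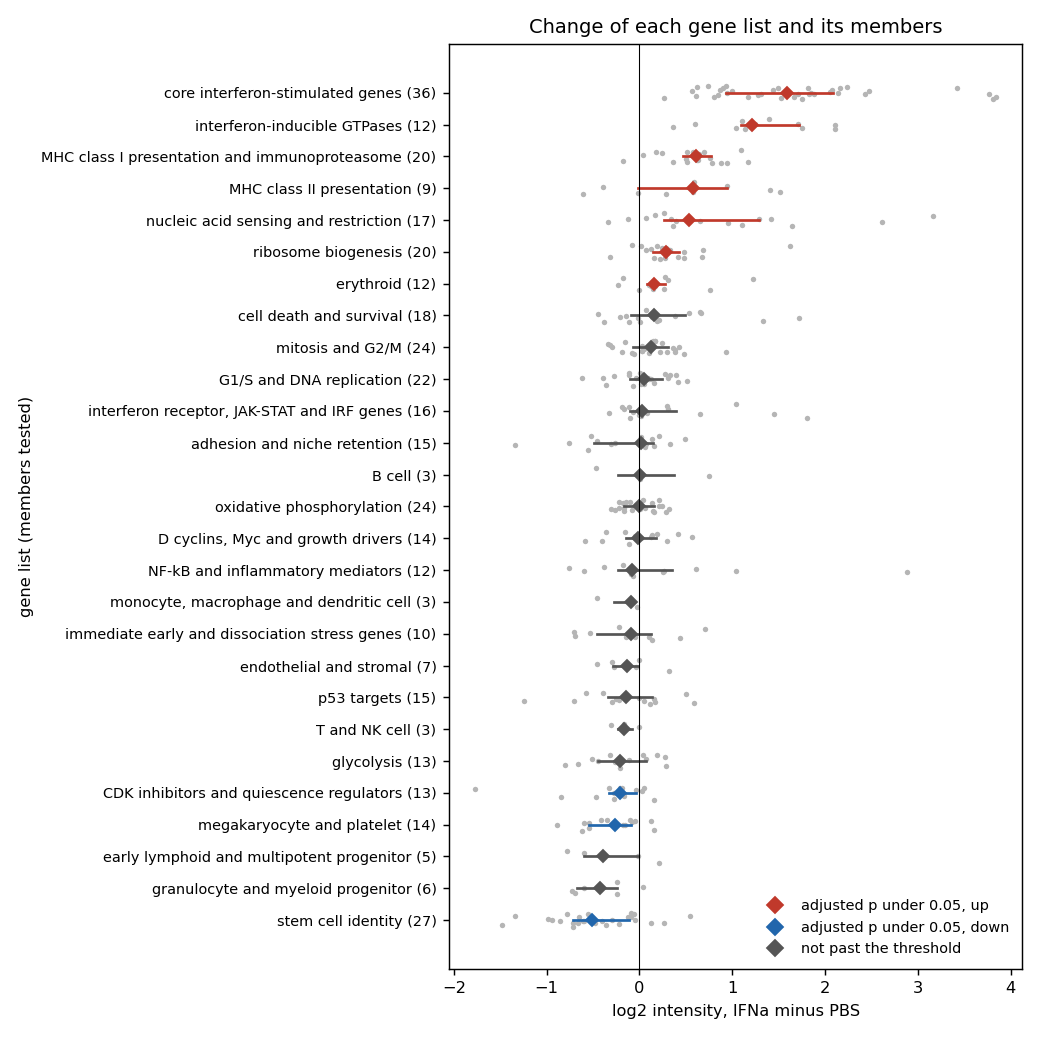
Log2 difference between IFNa and PBS (horizontal axis) for the 27 tested lists (vertical axis, with the number of tested members), each grey point a gene, each diamond the list's median and each bar its quartiles. Red and blue mark the 7 lists higher and 3 lower at a camera adjusted p under 0.05; the medians ran from -0.51 for stem cell identity to 1.59 for core interferon-stimulated genes.

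Markers of other blood cells were examined beside these lists, since a sorted gate can hold other cells. Erythroid markers were higher (median 0.16 over 12 members, camera adjusted p = 0.049), with 0 members past the threshold over all probes and 2 higher when adjusted over the list alone, Rhag at 1.22 ± 0.25 and Ermap at 0.76 ± 0.20 (other probe 0.31 ± 0.15). The call was lost with an estimated correlation (camera adjusted p = 0.372) and without PBS replicate 3, IFNa replicate 2 or IFNa replicate 3 (0.231, 0.0509 and 0.158). It was also lost with quantile normalization (0.0504), with probes above background on all 6 arrays (0.0758) and with the replicate number as a block (0.0698). With an array left out the erythroid median ran from 0.127 to 0.255. Megakaryocyte and platelet markers, of which 14 of the 17 on the array gave enough signal in these cells to be tested, were lower (median -0.26, camera adjusted p = 0.033), with 0 members past either adjustment and von Willebrand factor, Vwf, at -0.89 ± 0.21 (limma adjusted p = 0.134). That call was lost with an estimated correlation (camera adjusted p = 0.471), with no filter on dim probes (0.052) and with the 5% background tail (0.0954). It was also lost without PBS replicate 3 or IFNa replicate 3 (camera adjusted p = 0.068 and 0.251). With an array left out the megakaryocyte median ran from -0.422 to -0.169. Granulocyte and myeloid progenitor markers had a median of -0.42 over 6 members (adjusted p = 0.112), and with an array left out the median ran from -0.58 to -0.17 and the adjusted p from 0.0322, without IFNa replicate 3, to 0.306, with Ctsg at -0.73 ± 0.18. Early lymphoid markers had a median of -0.39 over 5 members (adjusted p = 0.192), with Cd27 at -0.60 ± 0.14. Monocyte, macrophage and dendritic cell markers had a median of -0.09 over 3 members (adjusted p = 0.327), with Lyz2 at -0.45 ± 0.14. B cell markers had a median of 0.01 over 3 members (adjusted p = 0.578), with Vpreb1 at 0.74 ± 0.16, and T and NK cell markers had -0.17 over 3 members (adjusted p = 0.396), with Lat at -0.31 ± 0.16. Endothelial and stromal markers had a median of -0.13 over 7 members (adjusted p = 0.578), with Sparc at 0.32 ± 0.17. In these 6 lists 0 members passed over all probes in limma, and adjusted over the list alone 2 granulocyte, 1 early lymphoid and 1 monocyte marker were lower and 1 B cell marker was higher.

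The other lists did not pass. Cell death and survival genes had a median of 0.15 over 18 members (adjusted p = 0.112). With an array left out the median ran from 0.02 to 0.17 and the adjusted p from 0.0476, without IFNa replicate 1, to 0.269. Daxx, a nuclear histone chaperone, rose by 1.72 ± 0.18, although it passed in 1 of the 6 fits with an array left out, and it was the 1 member whose brightest probe passed over all probes, while 4 were higher and 1 lower when adjusted over the list alone. Another probe of Mlkl, the effector of necroptosis, passed at 1.14 ± 0.17 (limma adjusted p = 0.0495). NF-kB and inflammatory mediators had a median of -0.08 but a mean of 0.24 and a test in the upward direction (adjusted p = 0.574) over 12 members. Of these, Cxcl10 passed over all probes and 2 were higher when adjusted over the list alone. For p53 targets the median was -0.15 over 15 members (adjusted p = 0.327), and Trp53inp1 was the 1 member lower by either adjustment. Glycolysis genes had a median of -0.21 over 13 members (adjusted p = 0.327), with Pgam1 at -0.66 ± 0.15 (other probe -0.09 ± 0.14) and 1 member lower when adjusted over the list alone. Oxidative phosphorylation had a median of 0.00 over 24 members (adjusted p = 0.968), with Sdhd at -0.27 ± 0.15 and 0 members past either adjustment. Immediate early genes had a median of -0.10 over 10 members (adjusted p = 0.578), with Zfp36 at -0.71 ± 0.14, and 1 higher and 1 lower when adjusted over the list alone. Adhesion genes had a median of 0.02, a mean of -0.18 and a test in the downward direction over 15 members (adjusted p = 0.537), with Cd9 at -0.52 ± 0.15 and 0 past either adjustment.

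Of the sorting markers, Kit and Slamf1 were tested, too few for a list test. Kit, the stem cell factor receptor, fell by 1.08 ± 0.17 by its brightest probe (limma adjusted p = 0.0495), and its other 2 probes read -0.46 ± 0.38 and 0.01 ± 0.17. It passed in 0 of the 6 fits with an array left out. Slamf1, which encodes CD150, differed by 0.11 ± 0.35 (limma adjusted p = 0.922). Since sorting selects on such markers, their levels between the groups are not a finding.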

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

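Of the settings here, the normexp correction, quantile normalization, cyclic loess, median centring, the filter on all 6 arrays and the 5% background tail were chosen after seeing the data. The 88 called genes kept their sign in every setting except with probes above background on all 6 arrays, where 70 of the 71 still measured did. The exception was Rnmt, at -1.07 by its brightest probe and 0.089 there, where only its other probe was left. A change of sign was counted where the gene or list passed under at least 1 of the settings compared. Against 62 genes higher and 26 lower, leaving out an array gave 14 to 25 higher and 1 to 4 lower, with fewer samples in each such fit, and 5 to 9 lists higher and 2 to 3 lower. An adjusted p under 0.01 left 18 higher and 0 lower in limma, with 792 and 921 at an unadjusted p under 0.05. Genes lower numbered 41 with a variance trend and robust fit, 43 with array weights, 40 with probes above background on all 6 arrays and 11 with normexp at either offset. The cause was not tested for these settings. Other counts stayed within 1.5 times, from 42 to 76 genes higher. With an estimated correlation, camera called 4 lists higher and 1 lower in place of 7 and 3, and with the 5% tail 1 list was lower (the cause was not tested). By fry 6 were higher and 3 lower, the interferon receptor list (adjusted p = 0.0125) and the monocyte list (0.0296) passed, and the erythroid, megakaryocyte and MHC class II lists did not (0.113, 0.153 and 0.107). The labels do not say whether replicate numbers pair the samples. Arrays of one number had deviations correlated at 0.003, -0.012 and 0.036, beside -0.049 to 0.042 for arrays of different numbers. With the number as a replicate block, limma called 0 genes higher and 0 lower (722 and 871 at an unadjusted p under 0.05), 6 lists higher and 2 lower. Such a block leaves fewer degrees of freedom to estimate the spread. Signal over background limits dim genes most: 27443 probes were not tested, and folds near background are understated. The planned neqc correction, its offset of 50, log2 of the unnormalized signal, filters on detection p-values and a slide block were not run.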

Other observations

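The tests of adjacency, of equally bright genes, of other cells' markers, of erythroid markers, of dim lower genes, of the authors' normalization and of dim probes on IFNa replicate 1 were chosen after the result was seen; the others were set before. Those of dim lower genes, of normalization and of dim probes replaced tests set before the result was seen, whose outcome the filter on dim probes and the common scale of the arrays had largely fixed, since normalizing scaled values again cannot undo the authors' step. Outside the fixed lists, 25 genes were higher and 24 lower, and those named in this paragraph were chosen after their values were seen. Plac8 rose by 1.86 ± 0.24, Gbp10 by 1.80 ± 0.25, the ubiquitin ligase Rnf213 by 1.77 ± 0.18, the class I gene H2-T24 by 1.33 ± 0.14, the nuclear body protein Pml by 1.22 ± 0.13 and Nampt, an enzyme of NAD synthesis, by 1.21 ± 0.18. Among genes that fell were Vezf1 by 1.12 ± 0.15, the lysosomal membrane protein Lamp1 by 1.05 ± 0.12 and the syndecan Sdc2 by 1.04 ± 0.13. With an array left out, Rnf213 passed in 2 and Gbp10 in 1 of the 6 fits, and the other genes named so far in 0. The largest negative difference over all tested genes missed the threshold: Matn4, a matrix protein, was at 11.78 ± 0.67 (SD) in PBS and 8.19 ± 1.03 in IFNa, a difference of -3.59 ± 0.56 (SE), with a limma adjusted p of 0.0503.

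Genes that rose lay next to each other more often than random genes. Of the 60 higher genes placed on the chromosomes, 7 pairs were direct neighbours among tested genes, against at most 2 in all but the highest 2.5% of 10000 random draws and a maximum of 5 (permutation p = 1e-04, the smallest these draws can give). The pairs were Oas2 with Oas3, Oasl1 with Oasl2, Gbp3 with Gbp7, Rsad2 with Cmpk2, Igtp with both Irgm2 and Gm12250, and Mndal with Ifi203, and 3 of the 7 share a symbol stem. A shared stem is a matter of naming and misses related genes with unlike symbols. Igtp and Irgm2, for example, are both in the list of interferon-inducible GTPases. The other pairs are therefore not shown to be unrelated genes. Neighbours may respond together through duplicated genes or shared regulation, and probes that bind paralogs could add to this. The 105 neighbours of higher genes that were not called had a median difference of 0.06. Of 303 families of genes with a common symbol stem, 5 passed camera, and 1 of these, the mitochondrial ribosomal Mrps genes, had no member in a fixed list. The others were Oas, Gbp, Ifi and Psmb. With an estimated correlation camera called none of the 303 families (adjusted p = 0.913 for each of the 5, and no lower for any other family). Even Oas, with all 6 tested members positive and a median of 1.56, did not pass there. That setting therefore does not tell the 5 from the other families, and the loss of their calls says little about them. The 27 tested Mrps genes had a median of 0.22, with 21 positive (camera adjusted p = 0.0368).

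The fall of the stem cell identity list was set against technical explanations and against other cells in the gate. It was not due to IFNa replicate 1 alone, since the median without it was -0.541 (camera adjusted p = 6.37e-06). The list also fell further than equally bright genes. Of 10000 random lists matched on brightness the median was -0.013 and the 2.5th percentile -0.16, against the list's -0.51. This largely repeats camera's comparison with other genes. The arrays already share a common scale, on which a general fall of equally bright genes could hardly show, so the comparison cannot exclude one. A lower share of stem cells stays open: 41 markers of the 7 types other than erythroid had a mean difference of -0.242, but 37 of them, with 14 megakaryocyte markers in the set, exceeded background on all 3 PBS arrays, a baseline that would hide a small share. A higher share of erythroid progenitors stays open too: the abundant markers Car1, Klf1, Aqp1, Tfrc and Car2 had a mean difference of 0.203, with 1 of the 5 above 2 SE, and the labels do not say whether the gate included Sca-1 or whether the sort on CD150 and CD48 removed such cells. A response of the stem cells themselves to IFNa may equally account for it and stays open as well.

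The 26 lower genes could reflect dim probes sinking into background or the authors' normalization. The former is argued against for 12 of the 26, among them Klhl24, Hspa2, Maged1 and Vezf1, whose probes stayed at least 2-fold above the background threshold on every IFNa array. For 13 of the others, Rprm, Wtip and Itga9 included, a loss of dim signal on the IFNa arrays stays open. These 13 lay at least 2-fold above the threshold on every PBS array. Over 5490 probes as bright in PBS the median difference was -0.048 (SD 0.465), beside -1.25 for the 13. The 13 were selected for their falls and the arrays share a common scale, so this comparison was largely fixed and cannot decide. For Osgin1, chosen after its values were seen and dim in PBS already, a loss of dim signal stays open too, at a difference of -0.89. Equally bright probes had a median of -0.02, but a single gene near the floor decides nothing. The values do not decide whether a normalization by the authors, acting as a curve of intensity on each array, played a part. Over 11858 probes as bright in PBS the median was -0.04 (SD 0.432), beside -1.12 for the 26. The 26 were selected for their falls and the arrays already share a common scale, so this comparison was largely fixed.

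IFNa replicate 1 correlated least with its group and had the highest background threshold, 215, and the fewest probes above it, 35.6%. Of 5192 dim probes that exceeded background on all 3 PBS arrays, 73.0% did so on this array, beside 80.5% and 86.9% on IFNa replicates 2 and 3, and at the common threshold of 215 the shares were 73.0%, 77.8% and 81.9%. Their median deviation from the other IFNa arrays was -0.003 on replicate 1, beside -0.018 and -0.012 on replicates 2 and 3. The arrays already share a common scale, so this median was largely fixed and cannot decide. The shares go with a weaker signal of dim genes on replicate 1, which stays open. The core interferon-stimulated genes of replicate 1 deviated by -0.059, beside a group difference of 1.67, so a different response of these genes in that sample is argued against. What set it apart stays open.

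Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split gave 88 genes and the highest other 0, and it gave 10 lists with the highest other at 5; in both cases 1 split, the real one, gave as many.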
